A study of Saccharomyces cerevisiae with 14 samples.

How the data were processed

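The series holds 14 spotted arrays of yeast with 2 channels, 1 per time point of an elutriation course, each with a reference pool in channel 1 and the time sample in channel 2, per the labels. The spots were read with ScanAlyze, version 2.03 for 9 arrays, 2.33 for 2 arrays and 2.44 for 3 arrays, per the labels. The dyes, strain, medium, background correction, spot filters and normalization are not given in the sources used here. The values used are the authors' deposited log2 ratios, 1 per probe and array. The log base was inferred from the values: 82 deposited values lay within 0.0006 of plus or minus the log2 of 2, against 9 at an offset 0.005 further out, and 30 against 1 for the log2 of 3, and the values ran from -13.628 to 5.644. The direction of the ratio and the normalization stay unknown. The deposited columns were not centred: their medians from 0 to 6.5 h were -0.102, -0.064, -0.153, -0.01, -0.023, -0.022, -0.016, -0.017, -0.016, -0.022, -0.025, 0.017, -0.07 and 0.002. Centring therefore moved the median of all genes by over 0.1 on the 0 h and 1 h arrays. No spot intensities were used here, so signal over background is unknown for every value.

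Of 7680 probes, 6458 carried 1 gene symbol in the platform annotation, none carried several, and 1222 were unnamed and left out. All 6458 were matched to current symbols through their gene identifiers. They stood for 5470 genes, 4545 with 1 probe and 925 with several, whose values were averaged. For 840 genes with 2 probes the median Pearson's r between probes along the 14 arrays was 0.478, with 148 below 0, against 0.021 for shuffled partners; for the 308 of these that were later called as varying it was 0.761, with 7 below 0. Probes measured on fewer than 12 arrays were left out, and with them 8 genes, which left 5462, of which 5301 had a value on all 14 arrays. Near-identical genes (CUP1 copies, histone pairs, ribosomal protein pairs, HXT6 and HXT7, TDH genes) can share signal on such arrays and are uncertain as single genes.

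Each array was centred on its median. A natural cubic spline of time with 4 degrees of freedom was fitted per gene with limma 3.58.1 in R 4.3.3, and the 4 coefficients were tested together with the moderated F-test and Benjamini-Hochberg adjustment over all genes tested. The size is the range of the fitted curve from 0 to 6.5 h on a grid of 0.1 h, with the SE of the difference between its highest and lowest point. The SE treats these points as given, and the highest minus the lowest point of a noisy curve is biased upward. A second limma fit tested a straight line in time. For each of 25 gene lists, the mean over members of the log2 ratio, centred per gene, gave 14 values, and the share of their variance explained by the spline was set against 100000 permutations of the time labels (one-sided), adjusted over the 25 lists; this tests for a smooth course of time and not against other genes. Fisher's exact test (two-sided) compared called members with all other genes tested. Intervals of peak times came from 1000 resamplings of member genes and leave out the error of the arrays. Peak times of single genes were compared between neighbouring cell cycle lists with 100000 permutations of genes (two-sided).

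The lists, the tests, the thresholds, the alternatives and the rule for naming genes were fixed before the data were examined, except 2 alternatives and some tests of the closing section, which were added later and are named as such. The rule named the 12 called genes with the largest fitted range and complete data, the 4 called members with the largest range of each cell cycle list and the 2 of each other list, the 5 complete called genes with the steepest slope in each direction, and CLN2, CLB5, HTA1, CLB2, SIC1, CTS1 and MCM3 whatever their values. The alternatives were no centring, scaling to one median absolute deviation, other limits on missing values, the software version as a covariate or 1 version alone, each array left out in turn, splines of 3 and 5 degrees of freedom, a cosine of a 6.5 h period, a threshold of 0.01, robust regression, the number in the lot label as a covariate, and the sign turned. The cosine was fitted together with a sine and a linear trend, and only the periodic part was tested. Added after the data were seen were genes with 1 named probe only and the course without its first 2 arrays. The software version and lot number were the only batch labels.

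The fits were tested on simulated data for 5462 genes, of which 200 were changed. The curve test called 10.4% of genes changed by 1.5-fold, 50.7% at 2-fold and 97.0% at 4-fold, with 5 false calls among 110. The slope test called 47.8%, 86.6% and 100% of genes with slopes of 0.1, 0.2 and 0.4 log2 per hour, all 156 with the right sign, with 14 false calls. The simulated slopes were straight lines, with noise sized by the scatter about the spline. In the data curvature counts as error of the slope test, so these 3 shares do not carry over. CUP1-1, for example, had a slope of -0.44 ± 0.15 and was not called (moderated slope test, adjusted p = 0.0652). Of 200 lists of simulated noise without a curve, 8 had a permutation p under 0.05. A simulated list made to peak at 3 h was placed at 3.1 h. The noise was independent between arrays and no measured genes were drawn, so this gives no rate for random lists of real genes. With only 200 genes changed, the curve test thus missed most simulated changes of 1.5-fold. This share does not carry over to the data, where 2171 genes were called and 1458 of them spanned at least 2-fold, the others less. Figures were drawn with matplotlib 3.10.9. No genome positions are given, as none came with the probes used here.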

Results

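Budding yeast (Saccharomyces cerevisiae) was followed along an elutriation time course with 14 arrays of 2 channels, 1 array per time point from 0 to 6.5 h in steps of 0.5 h. Elutriation separates cells by size in a centrifuge and is commonly used to collect small, unbudded daughter cells, which then pass through the division cycle together. Channel 1 held a reference pool and channel 2 the sample of each time point, per the labels. Each array measured between 7343 and 7476 of 7680 probes, and 5462 named genes were tested. No time point had a second array, so the error of every value is the scatter of the arrays about a smooth curve of time (9 residual degrees of freedom), and the p-values measure that scatter and not the spread between cultures. The number of arrays limits the precision. The question the design puts is which genes varied along the course, in what order, and by how much.

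The direction of the ratio was not settled by the labels. It was read as time sample over reference pool, which is likely but not certain. Channel 2 held the sample, and with this sign the chitinase gene CTS1, which acts in mother-daughter separation, was high at 0 h (log2 ratio 2.09). The mitotic cyclin gene CLB2 (-2.39) and the G1 cyclin gene CLN2 (-1.88) were low at 0 h, as is known for newborn daughter cells. All neighbouring arrays correlated above 0 across genes (Pearson's r 0.26 to 0.77, mean 0.56; genes are not independent replicates), so the arrays were taken to run the same way. Over all probes, unnamed ones included, the lowest r of any pair was 0.0806. Over the named genes tested it was -0.319, between the 0 h array and another one. Centring does not change r, so these values differ through the probes used and their averaging per gene. With the opposite reading every peak below becomes a trough and rising becomes falling, while the counts and sizes of the curve and slope tests stay as they are. The tests on the order of peaks do not stay, and their values under that reading are given with them. Peak and lowest times of single genes are those of the fitted curve, unless an array is named.

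Of the 5462 genes tested, 2171 (39.7%) varied along the course, and 1458 of these had a fitted curve that spanned at least 2-fold. The metallothionein genes CUP1-1 and CUP1-2, the heat shock gene HSP30 and the cell wall gene SPI1 had fitted ranges over 5 on the log2 scale and were highest at 0 h. These sizes rest on the 0 h array, without which they were 2.91 ± 0.31, 2.95 ± 0.35, 2.29 ± 0.45 and 2.91 ± 0.19. CTS1, the separation genes DSE1 and DSE4, and POL30, which encodes the sliding clamp of DNA replication, had ranges of 4.65, 4.21, 4.53 and 4.42, and SRL1, a cell wall mannoprotein gene, one of 4.33. The median range was 1.18 among genes that varied and 0.54 among the others, and 248 genes that varied spanned at least 2 on the log2 scale. Calls were made with limma's moderated F-test over the curve at an adjusted p under 0.05; 2739 genes had an unadjusted p under 0.05. Without the 0 h array 1318 genes were called, 1153 of them among the 2171. Without both the 0 and 0.5 h arrays 858 were called, 778 of them among the 2171 (the latter setting was chosen after the data were seen).

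The array at 0 h stood apart. On it 1006 genes lay 2-fold or more from their mean on the other arrays, against 29 to 196 genes on each of the other 13 arrays, and its median absolute deviation was 0.716 against 0.319 to 0.426. Of the 1458 genes that spanned at least 2-fold, 573 were highest at 0 h and 716 were lowest at 0 h. A further 345 peaked after 1 to 2 h, 205 after 2 to 3 h, 118 after 3 to 4 h, and 105 at 6.5 h. The spline placed only 0.27% of these peaks after 0 to 1 h, so highs on the 0.5 h array may be counted at 0 h or after 1 to 2 h. PHO84 was highest on the 0.5 h array (0.98) with a fitted peak at 1.7 h. ARN2 was highest on the same array (1.58) with a fitted peak at 0 h. When the 0 h array was left out, 728 genes spanned at least 2-fold. Of these, 192 were highest and 232 lowest at 0.5 h, 223 peaked after 2 to 4 h, and 111 peaked at 6.5 h. Of the 76 genes named by the rule set beforehand, 25 had a range over 1.5 times smaller without the 0 h array. Besides the 4 above they were POL30 (2.89), CDC21 (1.88), PHO84 (1.43), RPS22A (1.18), ILV3 (1.10), STE2 (1.08), SAM1 (1.03), AGA1 (0.96), SAM2 (0.96), RPL6B (0.90), MCM7 (0.90), MCM2 (0.87), FAR1 (0.82), SPO11 (0.71), GPA1 (0.69), ACO1 (0.69), TUB4 (0.69), MCM3 (0.61), QCR8 (0.54), COX13 (0.51) and IDH1 (0.44), with the range without it in brackets.

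**Figure D1:**
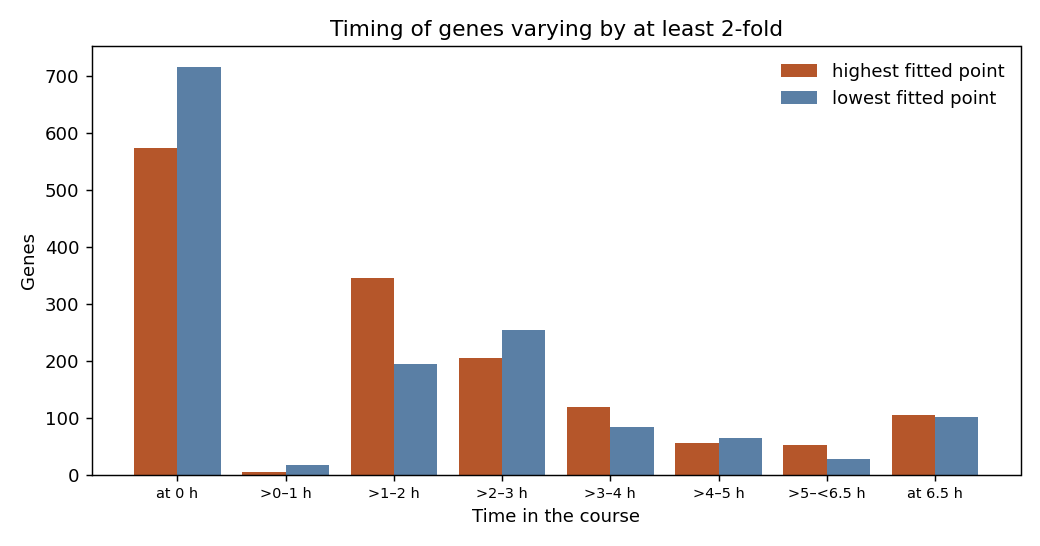
Number of genes (vertical axis) whose fitted curve was highest or lowest in each stretch of the time course in hours (horizontal axis), for the 1458 genes that varied by at least 2-fold. The bars at 0 h stand for 573 genes with their highest and 716 with their lowest fitted point.

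Genes of cell separation and of the M/G1 border were high at the end of the course. All 8 measured genes of the cell separation list varied. Their mean profile fell from 0.80 ± 0.34 (SE over 8 genes, each centred on its own mean) at 0 h to -1.19 ± 0.21 at 2.5 h, then reached 2.05 ± 0.30 at 6 h. The fitted profile spanned 3.22 on the log2 scale. CTS1 spanned 4.65 ± 0.28 (SE of the fit) with its lowest point at 2.7 h, and DSE1, a daughter-specific gene, spanned 4.21 ± 0.26. DSE4, a glucanase gene, spanned 4.53 ± 0.66 and SCW11, a cell wall glucanase gene, spanned 3.67 ± 0.21. All 11 genes of the SIC1-type list varied as well. SIC1, the inhibitor of the B-type cyclin kinase, spanned 1.43 ± 0.29, with a fitted curve lowest at 2.5 h and highest at 6.5 h. Its lowest array was at 0.5 h (-0.85) and its highest at 6 h (0.82). The chitin synthase gene CHS1 (2.05 ± 0.55), the cell wall gene PIR1 (2.03 ± 0.29), NIS1 (1.92 ± 0.21) and the Pho85 cyclin gene PCL9 (1.86 ± 0.34) had fitted curves that ended highest at 6.5 h, while the highest array of each was at 6 h. Adjusted over the list alone, 8 and 11 genes were called, as over all genes. The profiles followed a smooth curve of time more closely than permuted time labels allowed (adjusted permutation p = 0.00015 for the separation list and 0.00159 for the SIC1-type list). Within the 9 arrays read with 1 version of the scanning software, which end at 5 h, SIC1 (adjusted p = 0.141), CHS1 (0.215), PCL9 (0.0919) and the SIC1-type profile (adjusted permutation p = 0.153) did not pass. The ranges of the 3 genes there were 1.05 ± 0.41, 1.70 ± 0.64 and 1.59 ± 0.43. CHS1 also did not pass with the version as a covariate (0.0721), where its range was 2.10 ± 0.69, about as large but with a wider error.

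The third list of the M/G1 border, genes of the MCM type, was low mainly on the first array. Of its 10 members 9 varied, the same number as when adjusted over the list alone, and the mean profile was -1.05 ± 0.19 at 0 h and between -0.20 and 0.28 on all later arrays. CDC6, which loads the replicative helicase, spanned 2.07 ± 0.29 on the log2 scale, and FAR1, an inhibitor of the G1 cyclin kinase, 2.24 ± 0.38. The helicase subunit genes MCM2, MCM7 and MCM3 spanned 1.77 ± 0.24, 1.54 ± 0.23 and 1.32 ± 0.30. The list's profile passed (adjusted permutation p = 0.00025), but its peak time had a 95% interval of 1.7 to 6.5 h. Without the 0 h array 3 of the 10 were called, and MCM3 (adjusted p = 0.0709) and MCM7 (0.0571) were not. MCM3 was also not called without the 2.0 h array (adjusted p = 0.0555), where its range stayed at 1.35 ± 0.34, and within the 9 arrays of one software version the profile did not pass (adjusted permutation p = 0.0712).

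Late G1 genes were low at 0 h, and the profiles of both their lists peaked near 3 h. Of 16 late G1 cyclin, regulator and cell surface genes, 14 varied, and their mean profile was -1.30 ± 0.22 at 0 h and 0.71 ± 0.10 at 3 h. CLN2 spanned 2.99 ± 0.36 (7.92-fold) with its peak at 3.1 h, the repressor gene YOX1 3.44 ± 0.24 and CSI2 4.39 ± 0.96. The chitin transglycosylase gene CRH1 spanned 4.08 ± 0.34 but did not peak near 3 h, with its fitted peak at 6.5 h and its highest array at 6 h (0.91). The S phase cyclin gene CLB5 spanned 0.86 ± 0.22 and peaked at 2.7 h. Of 25 genes of DNA replication, repair and cohesion, 20 varied, with a fitted profile that peaked at 2.8 h (95% interval over genes 2.6 to 3.0 h). Among them were POL30 (4.42 ± 0.23, peak at 2.5 h), the thymidylate synthase gene CDC21 (3.41 ± 0.31), POL12, a subunit of DNA polymerase alpha (3.32 ± 0.24), and RNR1, the large subunit of ribonucleotide reductase (3.03 ± 0.35). Adjusted over the list alone, 14 of 16 and 22 of 25 were called, and the adjusted permutation p of the profiles was 0.000556 and 6.25e-05; the raw p of the second list was 1e-05, the smallest that 100000 permutations can give. Without the 0 h array 10 of 16 and 16 of 25 genes were called and CSI2 was not (adjusted p = 0.0534), nor was it without the 0.5 h array (0.0599) or the 3.0 h array (0.0543). Its range in these 3 fits was 4.25 ± 1.03, 3.55 ± 0.97 and 4.22 ± 1.06. Without both the 0 and 0.5 h arrays the range of CSI2 was 1.79 ± 0.91 (adjusted p = 0.436), so its size rests on the first 2 arrays. CLB5 was not called with the software version as a covariate (adjusted p = 0.0731), although its range there was 0.85 ± 0.24. Without the 0 and 0.5 h arrays CLN2 was not called (adjusted p = 0.059) and its range was 1.71.

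**Figure D2:**
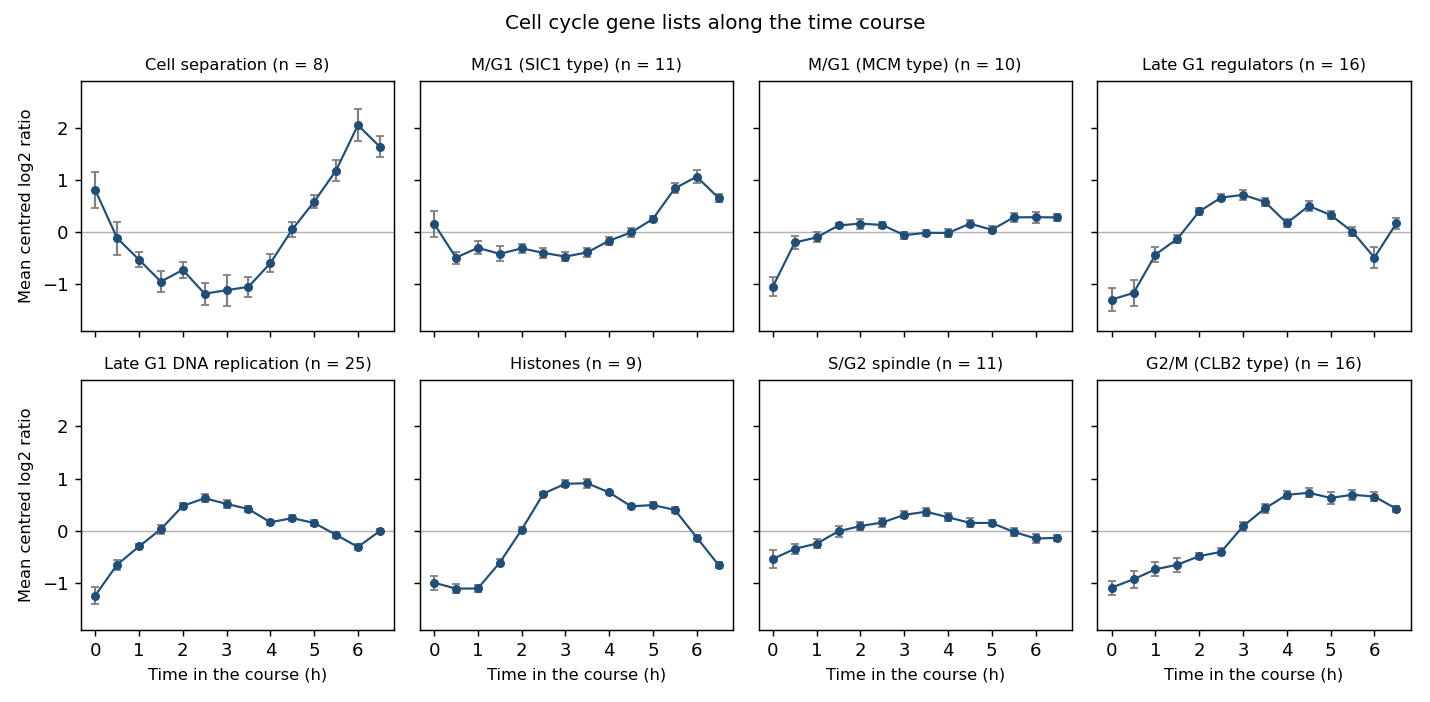
Mean log2 ratio of the genes of each cell cycle list, each gene centred on its own mean, against time in hours, with 1 array per time point; bars are the SE over the list's genes and n is the number of genes. The cell separation list reached 2.05 at 6 h, the late G1 regulators 0.71 at 3 h, and the histones 0.91 at 3.5 h.

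Histone genes varied together. All 9 core and linker histone genes varied, over all genes and adjusted over the list alone, and each spanned at least 2-fold. Their mean profile was -1.11 ± 0.06 at 1 h, 0.91 ± 0.09 at 3.5 h and -0.66 ± 0.06 at 6.5 h, and the fitted peak lay at 3.6 h (95% interval 3.5 to 3.6 h). HTA1, a histone H2A gene, spanned 2.02 ± 0.25 (4.06-fold), the H4 genes HHF1 and HHF2 2.73 ± 0.27 and 2.74 ± 0.24, HTA2 2.42 ± 0.25 and the H2B gene HTB2 2.30 ± 0.24. The adjusted permutation p was 0.000406, and all 9 genes were still called without the 0 and 0.5 h arrays. The copies of each core histone gene are near-identical, so their probes can share signal and the 9 genes are not 9 separate measurements.

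Spindle genes of S/G2 were lowest at 0 h and peaked in the middle of the course, and genes of the CLB2 type were high late. Of 11 spindle and kinetochore genes 8 varied, over all genes and adjusted over the list alone, and the fitted profile spanned 0.85 on the log2 scale with its peak at 3.4 h. CIK1, a kinesin-associated gene, spanned 1.91 ± 0.20, TUB4 and SPC98, of the gamma-tubulin complex, 1.73 ± 0.35 and 1.66 ± 0.17, and the microtubule polymerase gene STU2 1.22 ± 0.17. The share of called members did not pass Fisher's exact test against the other genes (adjusted p = 0.0662), while the profile did pass the permutation test (adjusted p = 6.25e-05). Without the 0 h array 6 of 11 were called and TUB4 was not (adjusted p = 0.228). Of 16 genes of the CLB2 type 15 varied, again the same number over the list alone, and all 16 rose by the slope test. CLB2 itself went from -2.39 at 0 h to 1.14 at 5 h and had a fitted range of 3.15 ± 0.26 (8.87-fold). CLB1, its paralog, spanned 3.27 ± 0.21, the polo kinase gene CDC5 2.80 ± 0.26 and the cytokinesis gene HOF1 2.73 ± 0.33. The list peaked at 5.0 h (95% interval 4.8 to 5.1 h; adjusted permutation p = 6.25e-05), and 14 of 16 were called without the 0 h array.

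The order of the lists was compared through the peak times of single genes. Histone genes peaked 0.995 h after the DNA replication genes (mean over 9 and 25 genes, permutation test, adjusted p = 0.00035), and CLB2-type genes peaked 2.19 h after the spindle genes (16 and 11 genes, adjusted p = 0.00014). Late G1 regulators had a mean peak 2.05 h earlier on the clock than the MCM-type genes (second minus first -2.05 h, permutation test, adjusted p = 0.00742). That order was not stable. Within the 9 arrays of one software version late G1 regulators peaked 0.59 h after the MCM-type genes (adjusted p = 0.159), and the test failed with the version as a covariate (-1.01 h, adjusted p = 0.189). The phases of the 2 list profiles under a cosine, 1.9 h for the MCM type and 2.8 h for late G1 regulators, also stood the other way round, although the peaks of single genes on that curve kept the order (-2.46 h, adjusted p = 0.00117). Histone and DNA replication genes kept their direction, but the test failed within the 9 arrays (0.439 h, adjusted p = 0.246), with the version as a covariate (0.816 h, 0.0697), with 5 spline degrees of freedom (0.42 h, 0.225) and without the 6.5 h array (0.592 h, 0.16). With the ratio read the other way the 3 differences were 0.043 h for histones (adjusted p = 0.699), -2.06 h for the CLB2 type (0.0573) and 0.725 h for late G1 regulators (0.592), so none passed. Separation and SIC1-type genes differed by 0.122 h (permutation test, adjusted p = 1), and SIC1-type and MCM-type genes by -0.649 h (0.548). Late G1 regulators and DNA replication genes differed by -0.541 h (permutation test, adjusted p = 0.135), and histone and spindle genes by -0.639 h (0.209). None of these 4 passed in the main fit; the SIC1-type and MCM-type lists did in 4 of the 14 fits without 1 array and with the ratio read the other way. These 7 tests permute genes between lists, and genes are not independent replicates.

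**Figure D3:**
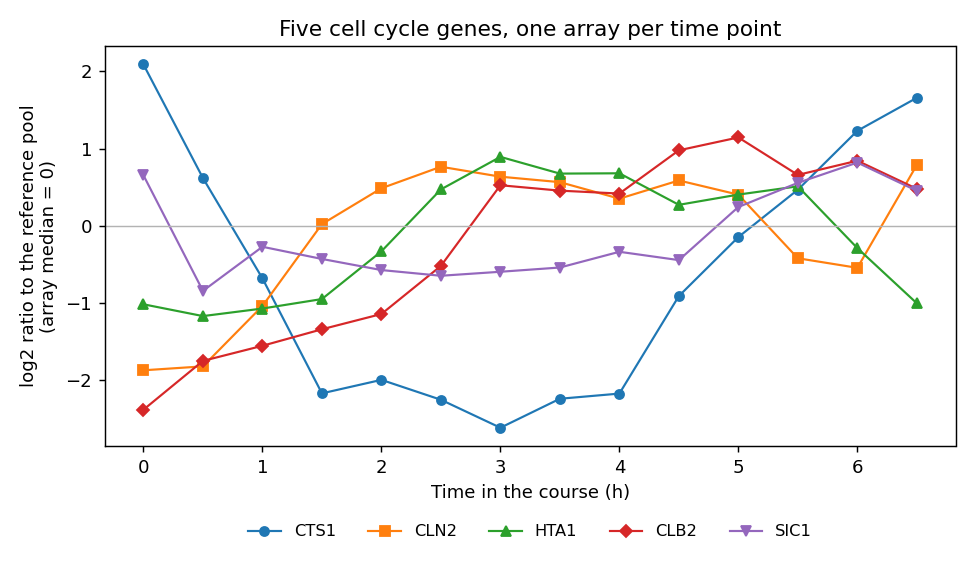
Log2 ratio to the reference pool, after each array was centred on its median, against time in hours for CTS1, CLN2, HTA1, CLB2 and SIC1; each point is 1 array. CTS1 fell from 2.09 at 0 h to -2.62 at 3 h, and CLN2, HTA1 and CLB2 were highest at 6.5, 3 and 5 h.

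Genes for making ribosomes were lowest at 0 h and highest near 2 h, and genes of the general stress response ran the other way. Of 119 ribosomal protein genes 112 varied (114 adjusted over the list alone). Their mean profile was -0.75 ± 0.04 at 0 h, 0.40 ± 0.02 at 2 h and -0.38 ± 0.02 at 6 h, with RPL6B and RPS22A spanning 2.04 ± 0.24 and 1.95 ± 0.39. Of 24 ribosome biogenesis genes 20 varied (22 over the list alone), and the mean profile went from -0.93 ± 0.09 at 0 h to 0.79 ± 0.07 at 2 h; NSR1, a nucleolar protein gene, spanned 2.62 ± 0.44 and NOP58, of the small nucleolar RNA particles, 2.30 ± 0.40. The profiles passed the permutation test with adjusted p = 6.25e-05 and 0.0012. Without the 0 h array 78 of 119 and 19 of 24 were called, RPS22A was not (adjusted p = 0.0675), and both profiles still peaked at 2.1 and 2.0 h. Many ribosomal protein genes exist as near-identical pairs, so their probes can share signal.

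Of 16 general stress and storage carbohydrate genes 14 varied (15 over the list alone), and of 17 chaperone genes 11 did (11 over the list alone). The stress profile was 1.49 ± 0.24 at 0 h, -0.91 ± 0.10 at 2.5 h and 0.68 ± 0.12 at 6 h, and the chaperone profile was 1.29 ± 0.32, -0.64 ± 0.11 and 0.49 ± 0.09 at the same times. SPI1 spanned 5.05 ± 0.27 (33.0-fold, and 2.91 on the log2 scale without the 0 h array), SOL4, a gene of the pentose phosphate pathway, 3.49 ± 0.58, and the heat shock genes HSP30 and HSP26 5.68 ± 0.66 (2.29 without the 0 h array) and 3.84 ± 0.48. CUP1-1 and CUP1-2, near-identical copies whose probes share signal, were at 4.46 and 4.36 at 0 h and below 0 from 1 h on. The profiles passed with adjusted permutation p = 0.00505 for stress and 0.00429 for chaperones, while the share of called chaperone genes did not pass Fisher's exact test (adjusted p = 0.0818). Neither profile passed without the 0 h array (adjusted permutation p = 0.0538 and 0.0605), where 11 of 16 and 5 of 17 genes were called, yet both passed without the 0 and 0.5 h arrays (0.0423 for each). The chaperone profile did not pass within the 9 arrays of one software version (adjusted permutation p = 0.0541).

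**Figure D4:**
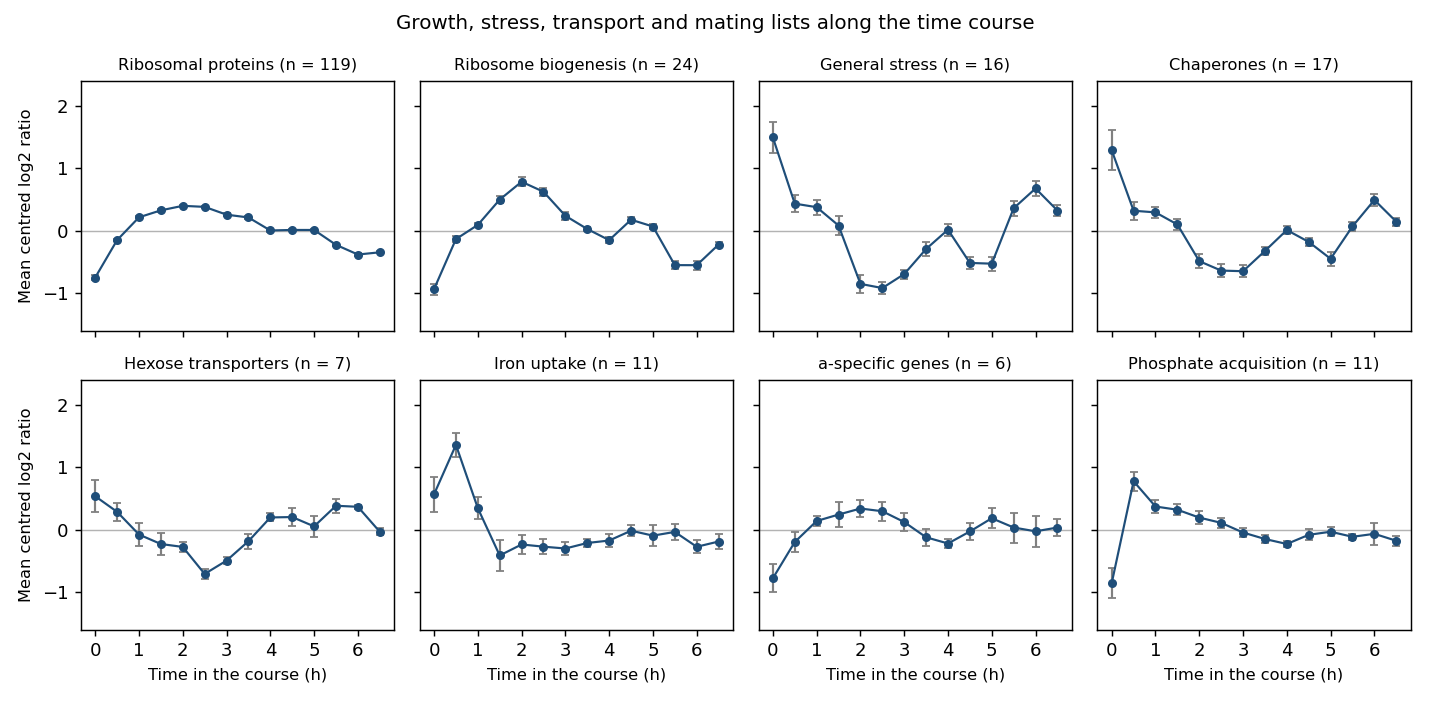
Mean log2 ratio of the genes of 8 further lists, each gene centred on its own mean, against time in hours, with 1 array per time point; bars are the SE over the list's genes and n is the number of genes. At 0 h general stress genes were at 1.49 and ribosome biogenesis genes at -0.93; at 2 h the latter were at 0.79.

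Among nutrient uptake lists the profiles of iron uptake and hexose transport passed the permutation test and that of phosphate acquisition did not. Of 11 iron uptake genes 5 varied (7 over the list alone), with a mean profile of 1.36 ± 0.19 at 0.5 h and -0.41 ± 0.25 at 1.5 h; FIT2, a cell wall gene that retains siderophore iron, spanned 3.69 ± 0.39 and ARN2, a siderophore transporter gene, 2.67 ± 0.36. The iron profile passed narrowly (adjusted permutation p = 0.0464) and missed the threshold under 19 of 24 alternatives (adjusted p between 0.0112 and 0.315 over all 24); without the 0 h array 9 of its 11 genes were called. FIT2 had a range of 0.54 without the 0 and 0.5 h arrays and was not called there (adjusted p = 0.58). Of 11 phosphate acquisition genes 3 varied (2 over the list alone), among them the transporter gene PHO84 (3.08 ± 0.63, -2.93 at 0 h and 0.98 at 0.5 h) and VTC3, of polyphosphate synthesis (1.57 ± 0.30). The shares of called iron and phosphate genes did not pass Fisher's exact test against the other genes (adjusted p = 0.829 and 0.646). The phosphate profile did not pass (adjusted permutation p = 0.178), yet it did without the 0 h array (0.000333), when 9 of 11 genes were called, without the 0.5 h array (0.00587) and without both (0.000417). PHO84 was not called with a curve of 3 degrees of freedom (2.18 ± 0.70, adjusted p = 0.0725), with the cosine (1.77 ± 0.70, 0.122) or without the 1.5 h array (2.91 ± 0.74, 0.0573). Of 7 hexose transporter genes 6 varied (6 over the list alone), including HXT5 (2.75 ± 0.31, highest at 0 h) and HXT3 (1.38 ± 0.23, lowest at 2.1 h), and the profile passed (adjusted permutation p = 0.00204). HXT6 and HXT7 are near-identical.

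Of 6 lists of carbon, amino acid and sulfur metabolism, only the profile of amino acid synthesis passed. For amino acid synthesis 9 of 16 genes varied (9 over the list alone), with ILV3 spanning 1.96 ± 0.19 and LYS9 1.51 ± 0.22. The profile passed (adjusted permutation p = 0.0164) but rested on the 0 h array (-0.64 ± 0.10 there), with an adjusted permutation p of 0.438 without it. It also missed the threshold without the 0.5 h array (0.0674), without both (0.777), with the software version as a covariate (0.0506) and within the 9 arrays of one version (0.137). The share of called genes did not pass Fisher's exact test (adjusted p = 0.32). Glycolysis had 9 of 15 genes called (10 over the list alone), among them ENO2 for enolase (1.38 ± 0.24) and TDH1 (1.35 ± 0.22). Its profile did not pass (adjusted permutation p = 0.0593), although it did without the 4.0 h array (0.0342), without the 5.0 h array (0.00548), with 5 spline degrees of freedom (0.0318) and without the 0 and 0.5 h arrays (0.0423). The TCA cycle had 5 of 13 called (5 over the list alone), the respiratory chain 6 of 21 (5), the glyoxylate and gluconeogenesis list 2 of 10 (2) and sulfur amino acid synthesis 3 of 13 (3). None of these 4 profiles passed (adjusted permutation p = 0.166, 0.144, 0.35 and 0.835). That of the TCA cycle did pass without the 5.0 h array (0.0285), within the 9 arrays of one version (0.00836), with 5 spline degrees of freedom (0.0312) and without the 0 and 0.5 h arrays (0.0423). The respiratory chain passed without the 0.5 h array (0.00192), and the glyoxylate and sulfur lists without the 0 h array (0.0232 and 0.0145). The respiratory chain and the glyoxylate list also passed without the 0 and 0.5 h arrays (0.0324 and 0.0261). Their called genes included aconitase ACO1 (1.38 ± 0.24) and IDH1 (0.98 ± 0.24), COX13 (1.33 ± 0.30) and QCR8 (1.32 ± 0.25). Others were the lactate dehydrogenase gene CYB2 (2.84 ± 0.40) and PCK1 of gluconeogenesis (1.93 ± 0.39), and the S-adenosylmethionine synthetase genes SAM1 (1.74 ± 0.41) and SAM2 (1.54 ± 0.38). Without the 0 h array IDH1 (adjusted p = 0.339), COX13 (0.18), QCR8 (0.253), SAM1 (0.158) and SAM2 (0.107) were not called, and SAM2 was also not called without the 2.5 h array (1.51 ± 0.41, adjusted p = 0.0516). Leaving that first array out gave 5 of 15 called glycolysis genes, 2 of 13 for the TCA cycle, 1 of 21 for the respiratory chain, 7 of 10 for the glyoxylate list and 5 of 13 for sulfur amino acid synthesis.

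Mating genes were measured because they mark cell type. Of 6 genes specific to a cells 5 varied (5 over the list alone), including STE2, the receptor for alpha-factor (1.78 ± 0.26, peak at 1.7 h), and BAR1, the protease that degrades it (2.21 ± 0.22, peak at 5.9 h). The profile passed (adjusted permutation p = 0.000321), while the share of called genes did not pass Fisher's exact test (adjusted p = 0.0764). Of 4 genes specific to alpha cells 1 varied (1 over the list alone), MF(ALPHA)2 (0.85 ± 0.12). The profile did not pass (adjusted permutation p = 0.178); it did over genes measured on all 14 arrays (0.00943) and without the 6.5 h array (0.0184). The difference between these lists was not tested. Of 8 pheromone response genes 4 varied (4 over the list alone), including the agglutinin gene AGA1 (1.60 ± 0.21) and GPA1, the G protein subunit (1.37 ± 0.26). The profile passed (adjusted permutation p = 0.0272), while the share did not pass Fisher's exact test (adjusted p = 0.819). The profile missed the threshold under 8 of 24 alternatives. These were the course without the 0 h array (0.0686), the 2.0 h array (0.0707), the 2.5 h array (0.0709) or the first 2 arrays (0.0926), and scaling of the arrays (0.0763). The others were the version as a covariate (0.0506), the 9 arrays of one version (0.0672) and 5 spline degrees of freedom (0.052). Of 13 meiosis and sporulation genes 3 varied (1 over the list alone) and the profile did not pass (adjusted permutation p = 0.835). SPS4 spanned 2.27 ± 0.23 and SPO11 1.22 ± 0.33, of which SPO11 lost its call in 13 of 28 alternatives (adjusted p between 0.00268 and 0.579). GPA1 was not called without the 0 h array (0.0695). Of all 25 lists, 17 profiles passed, among them the 8 cell cycle lists.

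Net change over the course was tested as a straight line. Among genes measured on all 14 arrays the steepest called rises were in 5 genes. CLB1 rose by 0.56 ± 0.08 log2 per hour (SE), DSE4 by 0.55 ± 0.16, CRH1 by 0.52 ± 0.08, CLB2 by 0.51 ± 0.06 and SCW11 by 0.50 ± 0.09. The steepest falls among these genes were in GIT1, a glycerophosphoinositol transporter gene (-0.51 ± 0.08), SPI1 (-0.49 ± 0.13), FIT3, a cell wall gene of iron retention (-0.35 ± 0.06), ICS2 (-0.33 ± 0.05) and ECL1 (-0.28 ± 0.05). FIT2, measured on 13 arrays, had a slope of -0.36 ± 0.11 (adjusted p = 0.0482), which lost its call in 15 of 23 alternatives and was 0.01 without the 0 and 0.5 h arrays. In all 267 genes rose and 241 fell by limma's moderated test at an adjusted p under 0.05, and 1529 genes had an unadjusted p under 0.05; 235 and 193 of them also varied by the curve test. Without centring of the arrays the split was 373 rising and 166 falling. The arrays read with the later software versions, 2.33 and 2.44, lie at 1, 4.5, 5.5, 6 and 6.5 h, so version and time are partly confounded. With the version as a covariate 77 genes rose and 32 fell, and within the 9 arrays of version 2.03 the counts were 62 and 18. With the version as a covariate the slopes of DSE4 (0.41 ± 0.18), SCW11 (0.39 ± 0.11) and SPI1 (-0.61 ± 0.16) did not pass, of which SPI1's was no smaller than in the main fit. Within the 9 arrays those of DSE4 (0.08 ± 0.23), SCW11 (0.17 ± 0.13) and GIT1 (-0.44 ± 0.14) did not pass. These arrays end at 5 h. The slope of SPI1 did not pass without the 0 h array (-0.29 ± 0.09), the 0.5 h array (-0.46 ± 0.14) or the 5.5 h array (-0.51 ± 0.14). Of these 3 fits only the first made it over 1.5 times smaller. Without both the 0 and 0.5 h arrays it was smaller still (-0.16 ± 0.08) and did not pass. That of DSE4 did not pass in 11 of the 14 fits without 1 array, in which it was 0.41 (without 6.0 h) or between 0.51 and 0.56. The rising count was 164 without the 5.5 h array and 160 without the 6.0 h array, and the falling count was 143, 106 and 114 without the 4.5, 5.5 and 6.0 h arrays.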

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

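The setting without the 0.0 and 0.5 h arrays and the one with only genes of 1 named probe were chosen after the data were seen; the others were planned. Against 2171 genes that varied, 1458 by at least 2-fold, 267 rising and 241 falling, scaling the arrays to one median absolute deviation gave 1420, 846, 173 and 131, with 1408 of the 1420 among the 2171. A threshold of 0.01 gave 1174 genes, robust regression 3738 (409 rising, 450 falling), and the cosine of a 6.5 h period 965 genes by at least 2-fold. With the software version as a covariate 77 genes rose and 32 fell, with the lot number 82 and 33, and within the 9 arrays of version 2.03 it was 62 and 18. Versions 2.33 and 2.44 lie mostly late in the course, so both version settings also take away part of the time axis. The lot number mostly rose along the course: from 0 to 6.5 h it was 61, 58, 60, 69, 70, 76, 77, 43, 79, 81, 63, 82, 83 and 84. Lot number and time are thus partly confounded too, and the lot setting also takes away part of the time axis. The strength of this relation was not tested. Without the 0.0 and 0.5 h arrays 858 genes varied, 529 by at least 2-fold, and 522 fell. Its slope for FIT2 was 0.0123 log2 per hour, opposite to the -0.36 over all arrays. Leaving out each array in turn gave 1318 (without 0.0 h) to 2669 (without 5.0 h) varying genes, and 728 (without 0.0 h) to 1708 (without 0.5 h) by at least 2-fold. It gave 160 (without 6.0 h) to 315 (without 6.5 h) rising and 106 (without 5.5 h) to 296 (without 5.0 h) falling. Under the settings of centring without scaling, missing values, software version, lot number, probes and splines, the counts of varying genes stayed within 1.5 times of the main ones. The rising and falling counts with the version or lot number, given above, did not. The cause of these changes in the counts was not tested.

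For lists, times with the cosine are phases of its periodic part without the linear trend. Peak times moved by more than the distance from the middle to the end of their 95% interval over genes, and by more than 0.1 h, in these cases. The separation list went from 6.5 h to 6.2 h with the cosine and to 0 h within version 2.03, and ranged from 6 to 6.5 h when single arrays were left out. The SIC1-type list went to 6.2 h with the cosine, 6.1 h with 5 spline degrees of freedom and 5 h within version 2.03, and ranged from 6 to 6.5 h over left-out arrays. Both lists were at 6 h without the 6.5 h array. The MCM-type list went to 1.9 h with the cosine and 1.6 h within version 2.03. Late G1 regulators went from 3.2 h to 2.8 h with the cosine, 2.7 h within version 2.03, and 3 h and 2.9 h with 3 and 5 spline degrees of freedom. They were at 2.9 h without the first 2 arrays and at 2.9 to 3.2 h over left-out arrays. DNA replication genes went from 2.8 h to 3.1 h after scaling. Histones went from 3.6 h to 4 h and 3 h with 3 and 5 spline degrees of freedom, 3.1 h within version 2.03 and 3.3 h without the first 2 arrays, with 3.3 to 3.7 h over left-out arrays. The CLB2-type list went from 5.0 h to 4.2 h with the cosine, 4.5 h with 5 spline degrees of freedom, 4.3 h within version 2.03 and 4.6 h without the first 2 arrays. With the sign of every ratio turned, the separation list peaked at 2.7 h, the SIC1-type list at 2.6 h, and the MCM-type, late G1 regulator, DNA replication, histone, spindle and CLB2-type lists all at 0 h.

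Of the 17 list profiles that passed, 15 still did after scaling, 14 with the software version as a covariate, 11 within version 2.03 and 14 without the first 2 arrays. A further 1 passed within version 2.03 and 5 without the first 2 arrays. Of the 76 named genes, 73 stayed called after scaling, 73 with the version as a covariate, 64 without the 0.0 h array, 62 with the cosine and 56 without the 0.0 and 0.5 h arrays. Lost after scaling were CSI2, MCM3 and QCR8, with the version CHS1, CLB5 and IDH1, and within version 2.03 CHS1, CLB5, MCM3, PCL9, SAM2 and SIC1. After scaling the range of QCR8 fell to 0.64. With the version the ranges (2.10, 0.85 and 0.91) were about as large as in the main fit. Within version 2.03 this held for CLB5 (0.92), MCM3 (1.26) and SAM2 (1.59), while CHS1, PCL9 and SIC1 had smaller ranges. Lost with the cosine were ACO1, BAR1, CHS1, COX13, FAR1, GPA1, IDH1, MCM3, MCM7, PHO84, SPO11, SPS4, STE2 and VTC3. Only the periodic part was tested there and not the linear trend. With the trend included, the ranges of BAR1 (2.19), SPS4 (2.32) and COX13 (1.34) were about as large as in the main fit. Others were smaller, such as those of PHO84 (1.77) and STE2 (0.98). The 20 lost without the first 2 arrays were AGA1, CDC6, CLN2, COX13, CSI2, FIT2, GPA1, IDH1, LYS9, MCM2, MCM3, MCM7, NOP58, QCR8, RPL6B, RPS22A, SAM1, SOL4, SPO11 and TUB4. Of 26 named slopes, 13 stayed called with the version or the lot number as a covariate, 12 within version 2.03 and 17 without the first 2 arrays. The order of MCM-type and late G1 genes reversed within version 2.03 (0.59 h) and with the sign turned (0.725 h), and that of spindle and CLB2-type genes with the sign turned (-2.06 h). The first of these orders lost its call in 9 more of 26 alternatives, and that of DNA replication and histone genes in 5.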

Other observations

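The list profiles hold some movements that the tests above do not cover. Late G1 genes were higher again on the last array: CLN2 was at -0.55 at 6 h and 0.79 at 6.5 h, RNR1 at -0.82 and 0.32, and the late G1 regulator profile at -0.49 ± 0.21 and 0.16 ± 0.11 (SE over 16 genes). Of 41 late G1 genes, 32 (78.0%) were higher at 6.5 h than at 6 h, with a median change of 0.29 on the log2 scale against -0.01 for all genes. Random lists of the same size had a median share of 46.3%. This share was computed after the rise had been seen and restates it, so it excludes no explanation, and the software versions of these 2 arrays differ (2.44 and 2.33). Histone genes went on down over the same step, with HTA1 at -0.29 and then -1.01. General stress genes had a smaller second high at 6 h (0.68 ± 0.12) when ribosome biogenesis genes were at -0.55 ± 0.07. Iron uptake, phosphate and sulfur lists were each highest on the 0.5 h array, at 1.36 ± 0.19, 0.77 ± 0.16 and 0.66 ± 0.21, while phosphate and sulfur genes were at -0.86 ± 0.23 and -0.45 ± 0.18 on the array before it. These are single arrays with no repeat.

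The tests on the general stress and ribosome biogenesis lists and the share of late G1 genes above were chosen after these profiles had been seen; the tests of chance order and of the 0 h array were set beforehand. To see whether chance orders of the arrays give as many calls, the time labels were put in 99 random orders. Only 1 of 100 orders, the real one, gave as many as 2171 varying genes, and the highest other count was 209. Likewise 1 of 100 orders, the real one, gave as many as 508 genes with a linear trend, and the highest other count was 2. Chance order can be excluded for both counts.

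The 0 h array stood apart from the 0.5 h array. Noise of single spots on it is argued against by 820 genes with 2 probes, whose changes from 0.5 h to 0 h correlated by r = 0.50 between probes, across genes that are not independent replicates; other neighbouring arrays gave 0.0625 to 0.25. A wider scale of that array could account for much of the count of distant genes, since 216 genes lay 2-fold or more from their mean on the other arrays after scaling, against 158 on the next array. A broad change of expression at 0 h would widen the scale in the same way, so the 2 are not separated. A bias with gene length is left open by Spearman's rho of -0.158 between length and the change, across 5451 genes. A change of state of the cells just after elutriation may remain as a hypothesis, and it cannot be told apart from the handling of that 1 array, since no time point had a repeat.

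General stress and ribosome biogenesis genes opposed each other along the course, with Pearson's r = -0.855 (permutation p = 9e-05) and Spearman's rho = -0.798 (permutation p = 0.00084) over the 14 arrays. The pair was picked after its profiles had been seen, so these were adjusted over all 300 pairs of lists (adjusted permutation p = 0.0018 and 0.0105). Of the 300 pairs 59 passed for r, and 6 had a lower r. The p-values over fewer arrays or over steps were not adjusted for the choice of the pair. Neighbouring time points are not independent. Over the 13 steps between arrays r was -0.89 (permutation p = 6e-05), but neighbouring steps share an array and are not independent either. Without the arrays farthest from the median stress level, 0 and 2.5 h, r was -0.73 (permutation p = 0.00619). Without the 0 and 0.5 h arrays r was -0.778 (permutation p = 0.00325, 95% interval -0.935 to -0.368), which argues against the 0 h array alone. Within the 9 arrays of software version 2.03 r was -0.867 (permutation p = 0.00426, 95% interval -0.972 to -0.479), which argues against the version alone. For the arrays after 0 h the version stays open, since r within 8 arrays of that version was -0.659 with a 95% interval of -0.931 to 0.085 (permutation p = 0.0795). The intervals and permutation p-values treat arrays or steps as independent. The normalization of the deposited values was not tested, and the design names no group, so no biological explanation was tested.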
